A study of Mus musculus with 7 samples.

How the data were processed

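Libraries had been prepared from total RNA of sorted cells with a targeted kit that amplifies 1 short amplicon per gene (Ion AmpliSeq Transcriptome, mouse), per the labels' protocols; the labels do not give the gates of the CMP and HSC sorts. The values are raw counts of reads per amplicon, as deposited by the authors in 1 table per sequencing chip; the genome build was mm10, per the submitters' processing notes. The aligner, the counting program and their filters are not given in the sources used here. Amplification without molecular identifiers means that reads are not independent molecules, so intervals and floors cover counting error only. A targeted panel sees 1 place per gene, and a sequence variant or a splice form that touches it changes the count without a change in expression. The tables held 23930 genes, of which 5957 had 0 counts in every library. Every column was matched to a sample by its barcode and table as the labels give them.

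Total counts ran from 7372430 (HSC) to 13854314 (LSK CD150+CD48+ replicate 2), with 10104 to 10620 genes at 10 or more counts per library. The 10 most abundant genes took 6.11 to 7.93% of the counts. A count of 0 allows up to 3 counts, a floor of 0.216 to 0.397 CPM (counts scaled to the library total).

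Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr (minimum count 10), which left 11429, and libraries were scaled with TMM factors. All 7 libraries entered 1 fit with a mean for each of the 4 groups, which left 3 residual degrees of freedom, and contrasts were tested with the quasi-likelihood F-test with robust moderation. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p under 0.05 is called. Every adjusted p of a single gene in the text comes from this test. Standard errors of log2 fold changes were derived from the same fit. CPM values use the TMM-scaled totals. No covariate is named in the labels, and strain and chip coincide in the CMPs, so no chip term was fitted. Genes whose counts are all 0 in a group are given as at least so many fold, against the floor.

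Lists of genes were fixed before the data were examined: 24 lists, for interferon and antigen presentation, lineages, cytokine receptors, IL-10, zinc, the cell cycle and metabolism, handling stress, the sort, and other cells. Of 574 entries 492 were in the tables. They were tested with camera (limma 3.58.1) on log CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 24 lists, beside camera with an estimated correlation and fry. The genes named were also chosen by a rule set before: the 8 genes with the largest increase and the 8 with the largest decrease among those called, with a mean of 20 CPM or more in the higher group, no overlap between the libraries of the groups and a proper gene name; up to 3 members with the smallest p of each list that was called or had 3 or more members called; and a fixed set of genes of the IL-10 and interferon-γ pathways, the lineages and the sort. Other genes are named only as examples of a list or a family, after their values were seen. For HSC against CMPs only the fixed set is named. Some genes that these rules pick are not reported here.

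The analysis was tested on simulated counts of 11429 genes. They had the totals of these libraries, the mean of each gene over all libraries and a dispersion per gene that was the same in every group. For pMT-10 against BL/6 CMPs the test recovered 81 of 100 genes changed by a log2 fold change of 2 and 27 of 100 changed by 1, and 12.9% of its calls were false. For LSK CD150+CD48+ cells against CMPs it recovered 75 and 30 (8.7% false), for HSC against LSK CD150+CD48+ cells 66 and 15 (8.99% false), and for HSC against CMPs 70 and 16 (10.42% false). Camera called the simulated list that had been shifted in each comparison, and not the others. Genes were simulated independently of each other and with equal spread in all groups. In the data the pMT-10 CMP pair differed more (SD of the log2 difference 0.823) than the BL/6 pair (0.385). The false shares and the result of camera may therefore not carry over to these libraries.

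Alternatives were RLE size factors, total counts without a composition factor, DESeq2 1.42.0, limma-voom, no filter on low counts, a minimum count of 50, a fold threshold, libraries thinned to the smallest total, each replicate left out in turn, only the groups compared, the replicate number as a block, and a contrast that subtracts the difference between the chips seen in the other groups. That difference also lies between LSK CD150+CD48+ cells and HSC, so cell population enters the contrast along with the chip. Limma-voom with library quality weights and a count without X- and Y-linked genes were added after seeing the data. Gene positions are those of the GENCODE M21 annotation, matched by symbol, which placed 89.1% of the genes. The positions are those of whole genes, since the places of the amplicons were not used here. No group had more than 2 libraries, so single libraries could not be tested as outliers and other splits of the samples were not counted. Figures were drawn with matplotlib.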

Results

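Targeted RNA sequencing measured 1 amplicon per gene in 7 libraries of sorted mouse bone marrow progenitors. The pMT-10 mouse carries an inducible Il10 transgene under a metallothionein promoter, which zinc switches on, and BL/6 (C57BL/6) mice served as controls. All mice had received zinc in the drinking water for 15 days. Common myeloid progenitors (CMPs), which give rise to granulocytes, monocytes, erythrocytes and megakaryocytes, were sequenced from pMT-10 mice (2 libraries) and BL/6 mice (2 libraries). From pMT-10 mice there were also 2 libraries of lineage-negative, SCA-1-positive, c-KIT-positive (LSK) cells that carried CD150 and CD48, and 1 library of haematopoietic stem cells (HSC). Totals ran from 7372430 to 13854314 counts per library. The pMT-10 CMP and LSK CD150+CD48+ libraries were read on one sequencing chip (chip 1) and the BL/6 CMP and HSC libraries on another (chip 2). The 2 pMT-10 CMP libraries differed more from each other (SD of the log2 difference across genes 0.823) than the LSK CD150+CD48+ pair (0.474) or the BL/6 pair (0.385). The labels do not say that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

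Il10 itself and the zinc response were looked at first. Il10 (chromosome 1, 131019845 to 131024974) had 0 counts in both pMT-10 CMP libraries, 0 and 1 in BL/6 CMPs, 0 and 2 in LSK CD150+CD48+ cells and 1 in the HSC library. These counts are at or under the floor of 3 counts per library, so no fold was formed and a difference in Il10 was not detectable at this depth in these progenitors. Mt1, a metallothionein induced by zinc, was at 719 ± 10.7 CPM (SD, n = 2) in pMT-10 CMPs and 688 ± 57.8 CPM (n = 2) in BL/6 CMPs, a log2 fold change of 0.06 ± 0.18 (SE, adjusted p = 0.815). The sign of this small difference turned without BL/6 replicate 1 (-0.025). Mt2 was not analysed here.

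The comparison of pMT-10 with BL/6 CMPs asks what IL-10 overexpression changes in this progenitor. Genes of MHC class II antigen presentation, which were nearly silent in BL/6 CMPs, were among the largest increases. H2-Eb1, a class II beta chain (chromosome 17, 34305867 to 34316674), rose from 0.473 ± 0.0163 to 247 ± 57.8 CPM (SD, n = 2 each), a log2 fold change of 8.99 ± 0.41 (SE, adjusted p = 2.53e-05). Cd74, the class II invariant chain, rose from 0.756 ± 0.416 to 203 ± 55.0 CPM (log2 fold change 8.02 ± 0.43, adjusted p = 2.77e-05). H2-Aa, H2-Ab1 and Ciita, the transactivator of class II genes, rose by log2 fold changes of 7.78 ± 0.57, 6.72 ± 0.50 and 6.06 ± 0.55. In total 3204 of 11429 tested genes passed an adjusted p of 0.05, 1638 higher and 1566 lower in pMT-10 CMPs, and 1947 of them differed at least 2-fold.

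Genes induced by interferon-γ rose together in pMT-10 CMPs. Of the 27 tested members of the interferon-γ list, 25 rose and 0 fell, with a median log2 fold change of 2.47, and 25 passed when adjusted over the list alone. The list stood apart from other genes (camera, adjusted p = 6.16e-12), with adjusted p = 0.342 with an estimated correlation. Gbp3 and Gbp4, guanylate-binding GTPases of cell-autonomous defence, rose by 3.89 ± 0.21 and 6.01 ± 0.63 on the log2 scale. Serpina3g, a serine protease inhibitor, went from 117 ± 4.90 to 715 ± 145 CPM (2.61 ± 0.21), and Irf1, a transcription factor of the interferon response, from 69.7 ± 9.14 to 375 ± 63.0 CPM (2.43 ± 0.21). The antigen presentation list had 19 of 21 tested members higher and 0 lower (21 when adjusted over the list alone, camera adjusted p = 1.45e-11). Its adjusted p was 0.345 with an estimated correlation, and it shares 5 tested genes with the interferon-γ list (Ciita, Nlrc5, Psmb8, Psmb9 and Tap1). Of 32 tested type I interferon genes 15 rose and 1 fell (16 and 3 when adjusted over the list alone, camera adjusted p = 0.00405, adjusted p = 0.404 with an estimated correlation). Zbp1, a sensor of nucleic acids in the Z conformation, led them with 3.49 ± 0.21, followed by Stat2 (2.21 ± 0.20), a signal transducer of the type I receptor, and Isg20, an exonuclease (2.18 ± 0.22). Ifngr2, the second chain of the interferon-γ receptor, rose by 1.38 ± 0.35, while Ifngr1 (-0.80 ± 0.30, adjusted p = 0.0732) and the IL-10 receptor gene Il10ra (0.16 ± 0.38, adjusted p = 0.779) did not pass the test.

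**Figure D1:**
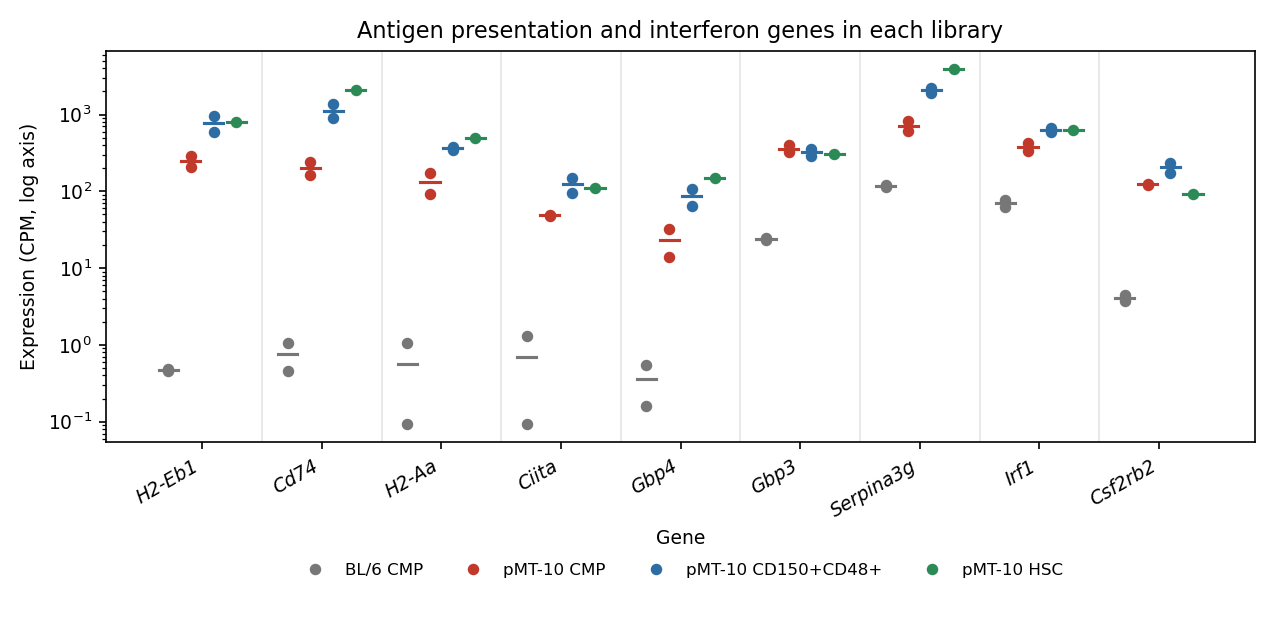
Expression of 9 antigen presentation, interferon and cytokine receptor genes, in CPM (counts scaled to the library total) on a log axis. Points are libraries and bars group means (2 libraries, 1 for HSC); H2-Eb1 averaged 0.473 CPM in BL/6 CMPs and 247 CPM in pMT-10 CMPs, and Irf1 69.7 and 375 CPM.

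Granulocyte genes were also higher in pMT-10 CMPs. Of 18 tested neutrophil and granule genes 8 rose and 0 fell (8 and 1 when adjusted over the list alone, camera adjusted p = 0.035, adjusted p = 0.345 with an estimated correlation). This call was lost without pMT-10 CMP replicate 1 (adjusted p = 0.0531), pMT-10 CMP replicate 2 (0.0746) or BL/6 replicate 2 (0.124). The azurophil proteases Elane and Ctsg rose by 2.70 ± 0.39 and 1.88 ± 0.27, and Ms4a3, a marker of granulocyte and monocyte progenitors, by 3.27 ± 0.42, whereas myeloperoxidase, Mpo, did not pass the test (7.20 ± 1.67 against 14.4 ± 3.33 CPM, adjusted p = 0.11). Of 11 tested basophil, mast cell and eosinophil genes 6 rose and 1 fell (6 and 1 when adjusted over the list alone, camera adjusted p = 0.0146, adjusted p = 0.345 with an estimated correlation). Ms4a2, the beta chain of the high-affinity IgE receptor, rose by 3.71 ± 0.38 on the log2 scale and Hdc, which makes histamine, by 2.96 ± 0.36, and the mast cell protease Cpa3 from 42.4 ± 5.32 to 170 ± 60.3 CPM. Gata2 was the gene that fell (-1.60 ± 0.26). Without pMT-10 CMP replicate 2 the call of this list was lost (adjusted p = 0.0759). Csf2rb, the shared beta chain of the GM-CSF, IL-3 and IL-5 receptors, and its near-identical neighbour Csf2rb2 rose by 3.42 ± 0.23 and 4.91 ± 0.25. Reads of such close copies, and of the Gbp, Serpina3 and H2-Q families, may be split between members, so the value of any one member is uncertain. In the monocyte and dendritic cell list 4 of 17 rose and 0 fell (camera adjusted p = 0.0597), among them the Fc receptor gene Fcgr3 (2.44 ± 0.40), and Irf8 did not pass the test (-0.18 ± 0.21). In the megakaryocyte list 8 of 20 rose and 1 fell (adjusted p = 0.0978), with Selp at 1.96 ± 0.25, Fli1 at 1.47 ± 0.23 and Itga2b at 1.29 ± 0.22.

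Kit, the stem cell factor receptor, fell by 1.29 ± 0.25 on the log2 scale (118 ± 31.7 against 288 ± 20.8 CPM), and Gata1, the master regulator of erythroid and megakaryocytic genes, fell by 0.94 ± 0.25. Of 22 tested erythroid genes 4 fell and 0 rose (camera adjusted p = 0.0978), including Ermap (-3.43 ± 0.56) and Gfi1b (-0.88 ± 0.17), while Klf1 was at 0.15 ± 0.25 (adjusted p = 0.691). Of 31 stem and multipotent progenitor genes 2 rose and 5 fell (adjusted p = 0.9), with Mllt3 lower (-2.60 ± 0.44), Slamf1, which encodes CD150, lower (-0.85 ± 0.23) and Ly6a, which encodes SCA-1, higher (4.41 ± 0.60). Cd48 rose by 1.69 ± 0.33, and Cd34 did not pass the test (0.40 ± 0.27, adjusted p = 0.288). Of 34 proliferation genes 4 rose and 4 fell (adjusted p = 0.719); Tyms, which makes thymidylate, fell by 2.33 ± 0.29. Of 7 tested zinc and metal genes 3 fell and 0 rose (camera adjusted p = 0.0457, adjusted p = 0.345 with an estimated correlation): the zinc transporter Slc39a10 (-1.23 ± 0.23), Gclm, of glutathione synthesis (-0.70 ± 0.17), and the zinc exporter Slc30a1 (0.110 ± 0.156 against 1.88 ± 0.310 CPM). The call was lost without pMT-10 CMP replicate 1 (adjusted p = 0.206) or BL/6 replicate 2 (0.0572).

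Markers of other cells gave mixed values. Only 7 of 26 measured T and NK cell genes passed the filter on low counts, and 4 of them rose (camera adjusted p = 0.0115, adjusted p = 0.345 with an estimated correlation). They were Gzmb, a granzyme also made by other cells (18.8 ± 2.22 against 1.40 ± 0.375 CPM), Nkg7, a granule membrane protein (188 ± 43.9 against 73.9 ± 3.14 CPM), Thy1 (1.38 ± 0.32) and the chemokine Ccl5 (2.29 ± 0.75), and the call was lost without pMT-10 CMP replicate 2 (adjusted p = 0.0691). The list of 5 tested B cell and plasma cell genes was not called (camera adjusted p = 0.756, median log2 fold change -0.101 with a mean of 0.131), of 5 macrophage genes 2 fell (adjusted p = 0.121) and of 8 stromal and endothelial genes 1 fell (adjusted p = 0.0914). The remaining lists were not called: apoptosis and p53 targets (adjusted p = 0.562), glycolysis (0.719), haematopoietic cytokine receptors (0.312), IL-10 and STAT3 response (0.881), immediate early and heat shock genes (0.0978), lymphoid progenitor (0.404), oxidative phosphorylation (0.404), ribosomal proteins (0.314) and sort markers (0.535). With an estimated correlation camera called 0 of the 24 lists, with 2 at an unadjusted p under 0.05, and fry, which tests only whether a list's genes move one way, called 12. The Y-linked genes Ddx3y and Eif2s3y were at 0 counts in both BL/6 libraries and at least 113-fold and at least 82.3-fold higher in pMT-10 CMPs (floor of 3 counts per library). Xist, which is transcribed from the inactive X chromosome, had 11904 and 8140 counts in the pMT-10 CMP libraries and 9308 and 8745 in the BL/6 CMP libraries. The largest decreases that met the rule for naming were in Tceal3 (-3.66 ± 0.53), Dennd5a (-3.45 ± 0.33), Kctd1 (-3.25 ± 0.35), Trpc4ap (-3.22 ± 0.39), Copb1 (-3.07 ± 0.49), Qrich1 (-3.05 ± 0.39) and Fam111a (-2.99 ± 0.29), besides Ermap.

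Strain and sequencing chip coincide in the CMPs, so no value within a chip and no fit with a chip term could be had. They cannot be told apart by this comparison. Subtracting the difference between LSK CD150+CD48+ cells and HSC, which also lie on the 2 chips, left 2125 genes called, 1164 of them among the 3204. It turned the sign of Ms4a2 (-6.68), Hdc (-4.86), Cpa3 (-0.177), Nkg7 (-0.291) and Cd48 (-1.31). The subtracted difference is also one between cell populations, so these turns cannot be assigned to the chip. Ms4a2, for example, had 0 counts in the HSC library, and Cd48 was lower there than in LSK CD150+CD48+ cells. The count rested on single libraries, with 582 genes without BL/6 replicate 1, 764 without BL/6 replicate 2 and 5268 without pMT-10 CMP replicate 1, where the lone library of a group is assumed to vary like the others.

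**Figure D2:**
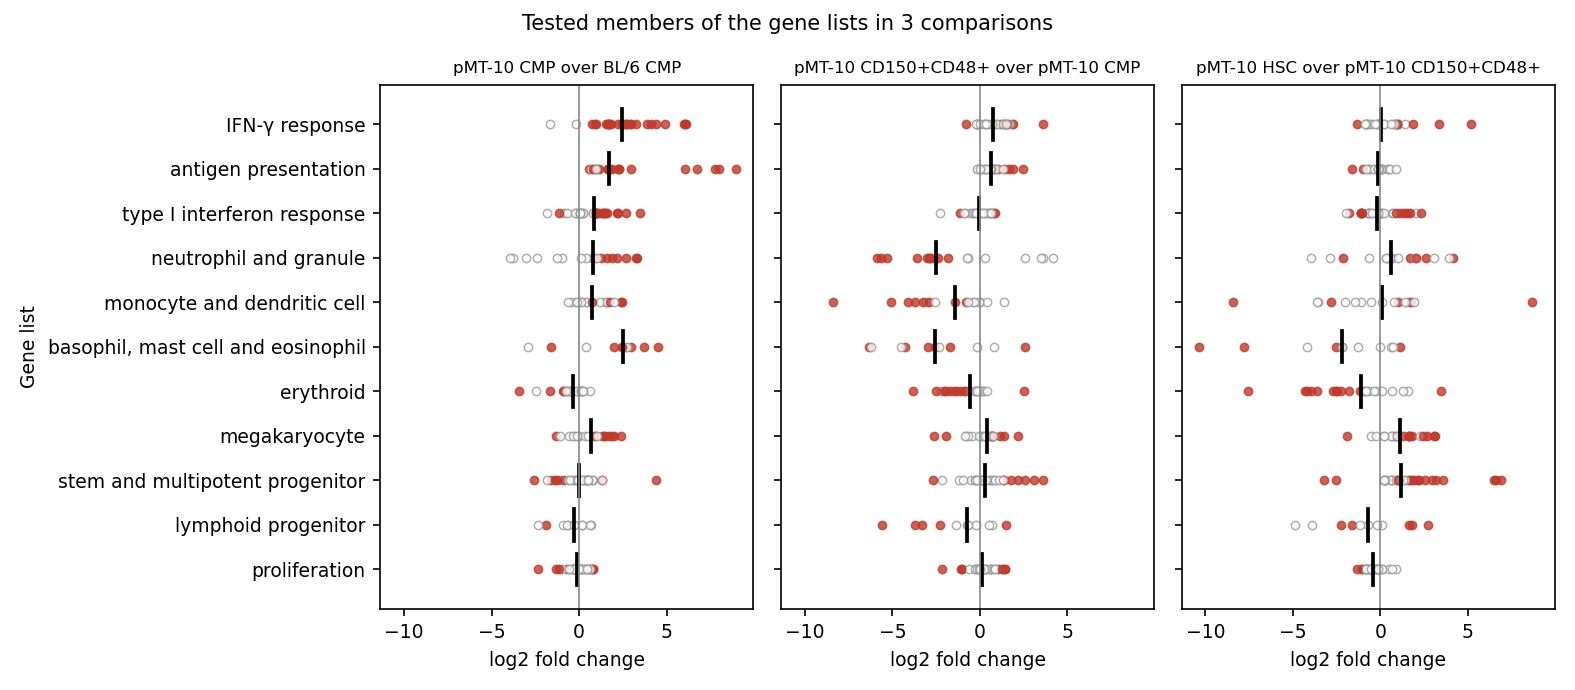
Log2 fold changes of the tested members of 11 gene lists in 3 comparisons; each circle is a gene, filled where its adjusted p was under 0.05 (edgeR), and each black bar is the median of the list. In pMT-10 over BL/6 CMPs the interferon-γ list had a median of 2.47, and in LSK CD150+CD48+ cells over pMT-10 CMPs the neutrophil list had a median of -2.50.

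LSK CD150+CD48+ cells and CMPs of pMT-10 mice were compared to see how the more primitive population differs in the same strain; both were on chip 1. Granulocyte and monocyte genes were far lower in LSK CD150+CD48+ cells. Ctsg was at 9.09 ± 1.36 against 364 ± 139 CPM in CMPs (SD, n = 2 each; log2 fold change -5.33 ± 0.32, adjusted p = 0.000162), and Csf3r, the G-CSF receptor, at 0.310 ± 0.273 against 20.8 ± 3.04 CPM (-5.85 ± 0.53, adjusted p = 0.000711). MHC class II genes were higher still than in pMT-10 CMPs, with Cd74 at 1124 ± 334 against 203 ± 55.0 CPM (2.47 ± 0.30, adjusted p = 0.00217) and H2-Eb1 at 773 ± 253 against 247 ± 57.8 CPM (1.64 ± 0.26). In total 1354 genes passed, 677 higher and 677 lower.

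Of 18 neutrophil and granule genes 10 fell and 0 rose (13 and 1 when adjusted over the list alone, camera adjusted p = 3.82e-06, adjusted p = 0.241 with an estimated correlation). Among them were Prtn3, an azurophil protease (-3.04 ± 0.24), Gfi1, a transcription factor of granulocyte differentiation (-5.64 ± 0.47), Elane (-2.38 ± 0.39) and Mpo (-1.81 ± 0.48). Of 17 monocyte and dendritic cell genes 8 fell and 0 rose (9 and 1 when adjusted over the list alone, camera adjusted p = 0.000311, adjusted p = 0.241 with an estimated correlation). Ctss, a lysosomal protease, had 0 counts in both LSK CD150+CD48+ libraries, at least 14.8-fold lower than in CMPs. Fcgr3 (-4.10), Ms4a6c (-2.88) and Irf8 (-0.79) also fell. The basophil, mast cell and eosinophil list had 1 of 11 higher and 5 lower (1 and 7 when adjusted over the list alone, camera adjusted p = 0.00137, adjusted p = 0.319 with an estimated correlation), with Hdc at -4.28 ± 0.40 and Cpa3 at -2.56 ± 0.27, and with Gata2 as the gene that rose (2.59 ± 0.27). Other genes with large decreases were Ccl9, a chemokine of myeloid cells (-5.79), the hexokinase gene Hk3 (-5.11), Cd53 (-4.87) and Tmem56 (-4.27). The lymphoid progenitor list had 1 of 11 higher and 4 lower (1 and 5 when adjusted over the list alone, camera adjusted p = 0.0371, adjusted p = 0.395 with an estimated correlation), with Dntt, the terminal transferase, at -5.60 ± 0.70 and Satb1 at -2.27 ± 0.28. Its call was lost without pMT-10 CMP replicate 1 (adjusted p = 0.084) or replicate 2 (0.0827). Of 22 erythroid genes 1 rose and 9 fell (1 and 10 when adjusted over the list alone, camera adjusted p = 0.00308, adjusted p = 0.625 with an estimated correlation), among them the transferrin receptor Tfrc (-1.69 ± 0.18), Sptb (-2.07 ± 0.29) and Sphk1 (-2.52 ± 0.39), whereas Klf1 (0.01 ± 0.25) and Gata1 (0.26 ± 0.25) did not pass.

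Of 31 stem and multipotent progenitor genes 7 rose and 1 fell in LSK CD150+CD48+ cells (9 and 2 when adjusted over the list alone, camera adjusted p = 0.0153, adjusted p = 0.319 with an estimated correlation, adjusted p = 0.0623 without LSK CD150+CD48+ replicate 1). Ly6a and Slamf1, members of this list whose products were used for the sort, rose by 3.60 ± 0.48 and 2.19 ± 0.23. Part of the rise of the list therefore follows from the sort. Cd34 fell by 2.67 on the log2 scale (25.6 ± 5.99 against 163 ± 61.2 CPM). Kit (-0.24 ± 0.24, adjusted p = 0.54) and Cd48 (-0.25 ± 0.31, adjusted p = 0.617) did not pass the test. Of 27 interferon-γ genes 8 rose and 1 fell (12 and 1 when adjusted over the list alone, camera adjusted p = 0.00137, adjusted p = 0.395 with an estimated correlation). Those that rose included Serpina3g at 1.53 ± 0.20, Gbp5 at 1.45 ± 0.20 and Irf1 at 0.73 ± 0.19. Ly6a, for whose product the LSK cells were sorted, is also a member of this list and among those that rose. Irf8 was the gene that fell. Of 21 antigen presentation genes 7 rose and 0 fell (10 when adjusted over the list alone, camera adjusted p = 0.000775, adjusted p = 0.536 with an estimated correlation, adjusted p = 0.0789 without pMT-10 CMP replicate 1). The type I interferon list was not called, with 1 of 32 genes higher and 1 lower (adjusted p = 0.964). Il10ra was lower in LSK CD150+CD48+ cells (-2.28 ± 0.42, adjusted p = 0.0119), and Ifngr1 (0.63 ± 0.30), Ifngr2 (-0.72 ± 0.34) and Mt1 (-0.58 ± 0.18) did not pass. The largest increases also took in Trpc4ap (4.86 ± 0.40), Tmem263 (4.09 ± 0.58), Casp4 (3.87 ± 0.52), Chuk (3.68 ± 0.54), Qrich1 (3.66 ± 0.39), Pfdn5 (3.66 ± 0.56) and Gtf2i (3.59 ± 0.42). Of these, Trpc4ap and Qrich1 stood at 2.13 and 7.55 CPM in pMT-10 CMPs and at 20.1 and 62.6 CPM in BL/6 CMPs.

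The count of 1354 fell to 44 without LSK CD150+CD48+ replicate 1 and to 96 without replicate 2, and was 4274 without pMT-10 CMP replicate 1 and 2705 without replicate 2. It was 595 when the 2 groups were fitted alone and 2237 with no filter on low counts.

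The HSC library was set against the LSK CD150+CD48+ libraries to place the stem cell within the pMT-10 hierarchy. Stem cell and megakaryocyte genes were higher and erythroid genes lower in the HSC library. Procr, which encodes the stem cell marker EPCR, was at 38.5 CPM against 0.360 ± 0.509 CPM (SD, n = 2; log2 fold change 6.46 ± 0.70, adjusted p = 0.00117), and Mecom, a transcription factor needed for stem cell maintenance, at 47.6 against 4.06 ± 0.0434 CPM (3.55 ± 0.34, adjusted p = 0.000738). Vwf, von Willebrand factor, was at 315 against 36.2 ± 2.48 CPM (3.12 ± 0.23, adjusted p = 0.000267), while the carbonic anhydrase gene Car1 was at 425 against 7964 ± 1279 CPM (-4.23 ± 0.31, adjusted p = 0.000267). In total 2145 genes passed, 1215 higher and 930 lower in the HSC library.

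Of 31 stem and multipotent progenitor genes 14 rose and 2 fell (18 and 2 when adjusted over the list alone, camera adjusted p = 1.15e-05, adjusted p = 0.252 with an estimated correlation), with Fgd5 at 6.58 ± 0.95 and Trpc6 at 2.95 ± 0.26, and with Gata2 (-2.52 ± 0.35) and Mllt3 (-3.22) as those that fell. Of 20 megakaryocyte genes 10 rose and 1 fell (11 and 2 when adjusted over the list alone, camera adjusted p = 0.00194, adjusted p = 0.335 with an estimated correlation), among them platelet factor 4, Pf4 (2.64 ± 0.29) and Selp (2.44 ± 0.28). Of 22 erythroid genes 1 rose and 12 fell (2 and 13 when adjusted over the list alone, camera adjusted p = 0.00016, adjusted p = 0.497 with an estimated correlation), with Klf1, an erythroid transcription factor, at -3.95 ± 0.43 and Aqp1 at -2.24 ± 0.24. Of 34 proliferation genes 3 fell and 0 rose (0 when adjusted over the list alone, camera adjusted p = 0.0206, adjusted p = 0.497 with an estimated correlation): Mki67 (-1.06 ± 0.32), Aurkb (-1.06 ± 0.24) and Foxm1 (-1.35 ± 0.36). With an estimated correlation camera called 0 lists here, with 2 at an unadjusted p under 0.05, and 0 in the comparison of LSK CD150+CD48+ cells with CMPs, with 3; fry called 9 in each.

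**Figure D3:**
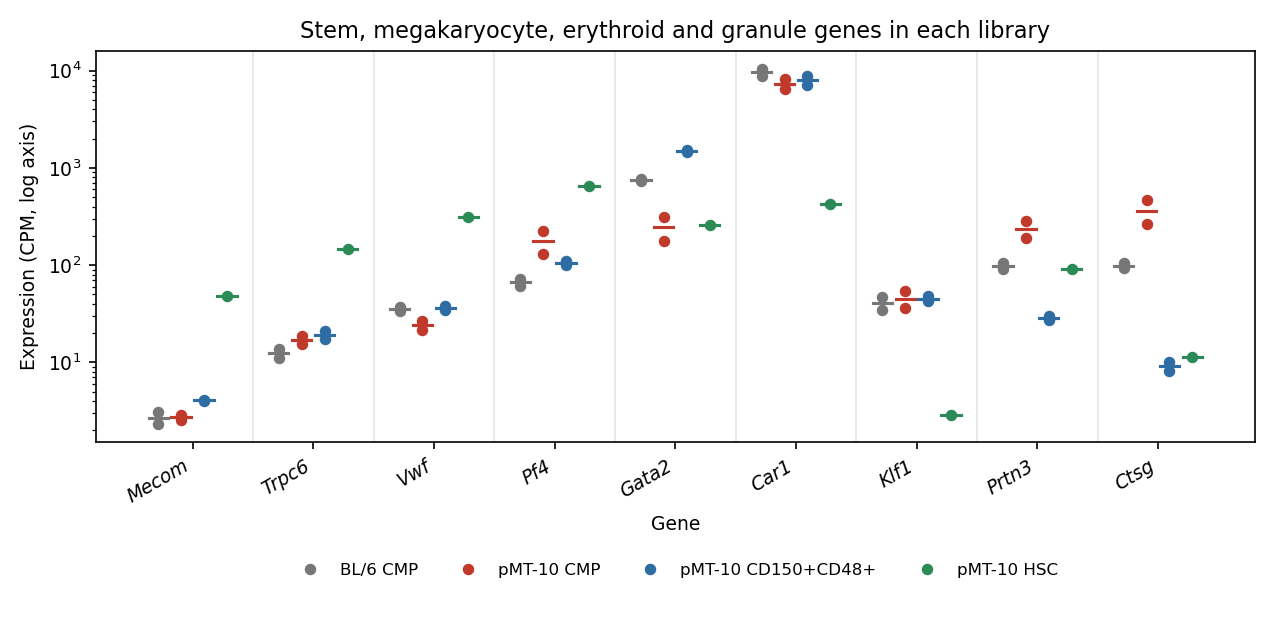
Expression of 9 stem cell, megakaryocyte, erythroid and granule genes in CPM on a log axis, with a point for each library and a bar for the mean of its group (2 libraries, 1 for HSC). Mecom stood at 47.6 CPM and Vwf at 315 CPM in the HSC library, where Klf1 stood at 2.91 CPM.

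The interferon-γ list did not differ as a whole between the HSC library and LSK CD150+CD48+ cells (5 of 27 higher, 2 lower, camera adjusted p = 0.756, median log2 fold change 0.007). Within it the chemokine genes Cxcl9 (201 against 5.48 ± 0.0176 CPM, 5.19 ± 0.42) and Cxcl10 (1.83 ± 0.41) and Serpina3g (0.95 ± 0.23) rose, while Irf1 stood at 0.01 ± 0.24. Ifngr1 (-1.46 ± 0.39) and Mt1 (-1.41 ± 0.24) fell, and so did Cd48 (6.48 against 52.0 ± 16.3 CPM), for whose product the LSK CD150+CD48+ cells were sorted. Il10ra (0.30 ± 0.56), Kit (0.66 ± 0.29), Slamf1 (0.66 ± 0.26) and Ly6a (0.21 ± 0.52) did not pass. Of 7 T and NK cell genes 2 rose and 2 fell (camera adjusted p = 0.772), of 5 B cell genes 2 rose, including Cd79b (1.70 ± 0.34), and 1 fell (adjusted p = 0.141), and of 5 macrophage genes 3 fell, including Apoe (-2.58 ± 0.28, list adjusted p = 0.0638). In the stromal and endothelial list 2 of 8 rose, among them Emcn (4.87 ± 0.58), and 1 fell (adjusted p = 0.129). Of the genes with the largest changes, Apol8 had 0 counts in both LSK CD150+CD48+ libraries and was at least 130-fold higher in the HSC library. Evc, of hedgehog signalling at the cilium, stood at 43.9 CPM (332 counts) in the HSC library against 1 and 0 counts in LSK CD150+CD48+ cells, and Myof at 36.2 CPM (274 counts) against 0 and 3 counts. Evc2 (6.99 ± 0.70), AY761185 (6.34 ± 0.74) and Spata25 (5.86 ± 0.70) also rose. Ermap (-7.56 ± 1.12), Tspo2 (-5.49 ± 0.45), Chuk (-5.27 ± 0.87), Atp1b2 (-5.27 ± 0.30), Trpc4ap (-5.18 ± 0.57) and Prss50 (-4.98 ± 0.51) fell, and St8sia6 and Fzd7 had 3 counts each in the HSC library (0.397 CPM) against 21.5 ± 5.24 and 20.5 ± 6.52 CPM.

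This comparison has 1 HSC library, assumed to vary like the others, and crosses the chips, so the cell population and the chip cannot be told apart in it. The count was 266 without LSK CD150+CD48+ replicate 1 and 352 without replicate 2, and 3481 with library quality weights in limma-voom, which were added after seeing the data.

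Between the HSC library and pMT-10 CMPs 2912 genes passed, 1580 higher and 1332 lower in HSC. Slamf1 rose by 2.84 ± 0.26 (adjusted p = 0.000374) and Ly6a by 3.80 ± 0.52, while Klf1 (-3.94 ± 0.43), Elane (-3.01 ± 0.54) and Cd34 (-1.10) fell. Mpo, lower by the test, had 2 counts in the HSC library (0.265 CPM) against 7.20 ± 1.67 CPM in CMPs. Irf1 rose by 0.74 ± 0.23 (adjusted p = 0.0446), and Ifngr2 (-1.81), Il10ra (-1.98), Mt1 (-1.99) and Cd48 (-3.25) fell. Ifngr1 (-0.83 ± 0.38), Irf8 (0.24 ± 0.26), Gata1 (-0.41 ± 0.31) and Kit (0.42 ± 0.29) did not pass the test. The chip and the population coincide here too; the count was 5222 without pMT-10 CMP replicate 1 and 4635 without replicate 2.

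A chip difference common to all libraries was looked for across genes. The log2 fold changes of pMT-10 over BL/6 CMPs were set against those of LSK CD150+CD48+ cells over HSC, which share no library and both put chip 1 over chip 2. Across the 11429 genes, which are not independent replicates, Pearson's r was -0.015 and Spearman's rho 0.044, and across the 3204 genes called between the CMPs r was -0.039 and rho 0.044.

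**Figure D4:**
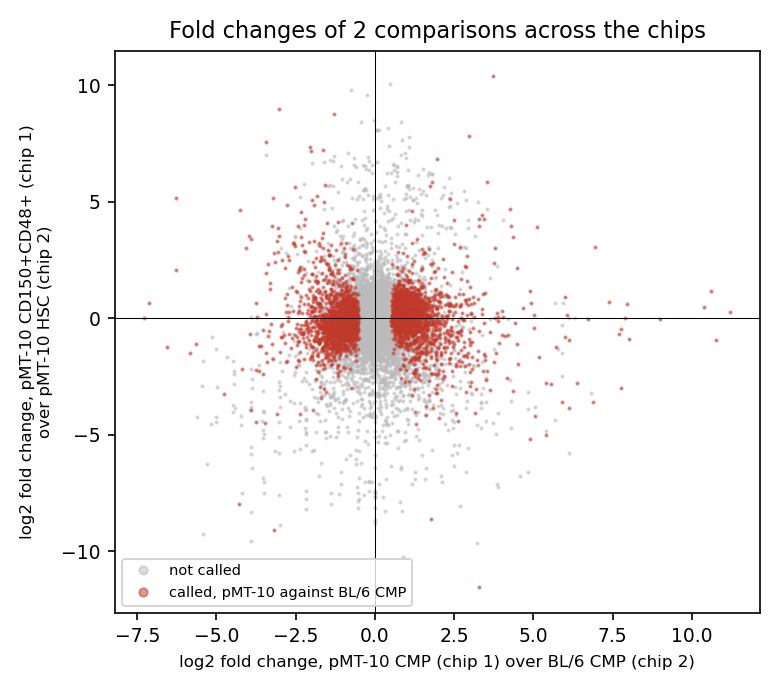
Log2 fold changes of 11429 genes in 2 comparisons that each put chip 1 over chip 2, with pMT-10 over BL/6 CMPs on the x axis and LSK CD150+CD48+ cells over HSC on the y axis. Red points are the 3204 genes called between the CMPs, and Pearson's r across all genes was -0.015.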

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

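The added fits, limma-voom with library quality weights and the count without X- and Y-linked genes, were chosen after seeing the data. Under RLE size factors, total counts only, DESeq2, limma-voom, the stricter filter and thinning, the counts of called genes stayed within 1.5 times in the 4 comparisons. The causes of the changes below were not tested, unless fewer libraries or a stricter threshold made them. With a log2 fold change of 1 or more the counts were 1947 for pMT-10 against BL/6 CMPs and 897 for LSK CD150+CD48+ cells against CMPs. The second count was 2237 with no filter and 595 with only the 2 groups. The chip-adjusted contrast gave 2125, and quality weights gave 3481 for HSC against LSK CD150+CD48+ cells. Leaving out 1 replicate gave 582 to 5268, 44 to 4274, 266 to 352 and 4635 to 5222 genes in the 4 comparisons in the order of the report. Of the 44, 29.5% were higher, against 50% of the 1354. The lists called in CMPs numbered 7, and 0 with an estimated correlation, 12 with fry, 12 in the chip-adjusted contrast and 4 to 10 with a replicate left out. With an estimated correlation 0 lists were called in the other comparisons (8 and 4 in the main result), and fry called 9 in HSC against LSK CD150+CD48+ cells.

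The replicate numbers did not pair the samples: same-numbered libraries of the 3 groups had correlations of their deviations of -0.019, -0.019 and -0.076. With the replicate number as a block 2979 genes were called between the CMPs (2880 shared with the main result) and 1181 between LSK CD150+CD48+ cells and CMPs (1122 shared).

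Signs turned in the chip-adjusted contrast between the CMPs for Ms4a2 (-6.683), Hdc (-4.858), Cpa3 (-0.177), Rps4x (-0.052), Nkg7 (-0.291) and Cd48 (-1.307), which were called in the main result, and for Mt1 (-1.345), Irf8 (0.845) and Klf1 (-3.802), which were not. Cell population enters this contrast too, so these turns cannot be assigned to the chip. The other turns were in genes not called. Between the CMPs these were Mt1 (-0.025 to 0.162 with a replicate left out), Il10ra (-0.005 thinned, -0.541 to 0.626 with a replicate left out), Klf1 (-0.157 to 0.398, with -0.058 without BL/6 replicate 1) and Cd34 (-0.041 to 0.742). Between LSK CD150+CD48+ cells and CMPs they were Klf1 (-0.034 with total counts, -0.004 thinned, -0.245 to 0.311 with a replicate left out), Gata1 (-0.067 to 0.561), Kit (-0.535 to 0.065) and Cd48 (-0.62 to 0.221). Irf1 in HSC against LSK CD150+CD48+ cells was at -0.022 with no filter, -0.014 with the stricter filter and -0.08 to 0.097 with a replicate left out. Of all named genes and settings, 3071 pairs kept their direction and side of the threshold, 259 lost the call, 29 gained one and 27 turned.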

Other observations

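The gene families and the comparison of the antigen-presenting cell markers were chosen after the results were seen; the tests of the chips, of library size and of the slope between the LSK CD150+CD48+ libraries were set before their results. All 6 tested guanylate-binding protein genes rose in pMT-10 over BL/6 CMPs (median log2 fold change 3.06). So did the 6 tested immunity-related GTPase genes, whose products attack the vacuoles of intracellular pathogens, among them Irgm1 (0.90 ± 0.17), Igtp (2.47 ± 0.54), Gm12250 (3.03 ± 0.19) and Gm12185 (4.93 ± 0.25). The others, Gm4951 and F830016B08Rik, had 0 and 1 and 0 and 0 counts in the BL/6 libraries. The interferon-induced proteasome subunits Psmb8, Psmb9 and Psmb10 and the activator Psme1 rose by 1.72 ± 0.27, 2.95 ± 0.26, 2.74 ± 0.25 and 1.16 ± 0.21, while the constitutive subunits Psmb6 (0.48 ± 0.28) and Psmb7 (-0.19 ± 0.18) did not pass the test. Of the 3 interferon-induced families the fixed lists held 6, 3 and 3 genes, so they are not independent of those lists.

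Of 20 tested replication-dependent histone genes 10 were lower and 0 higher in the HSC library than in LSK CD150+CD48+ cells (median log2 fold change -0.86), 3 were higher and 0 lower in LSK CD150+CD48+ cells than in CMPs (0.33), and 4 were lower and 0 higher in pMT-10 than in BL/6 CMPs (-0.49). Of 9 tested Hox genes 2 were higher in the HSC library than in LSK CD150+CD48+ cells, Hoxb2 (4.23 ± 0.76) and Hoxa7 (0.98 ± 0.26). Near-identical histone genes may share reads, and chip and population cannot be told apart in the HSC comparison, in which the slope test below (-0.029) bears only on differences common to all libraries.

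The first pattern is the 3204 genes called between pMT-10 and BL/6 CMPs. A chip difference common to all libraries would return between LSK CD150+CD48+ cells and HSC, but the slope across the called genes was -0.029 (bootstrap SE over genes 0.017), which argues against it, with the limit of 1 HSC library; a batch effect of the CMP libraries alone stays open. Library size is argued against too, since 93.1% of the calls held after thinning. Y-linked transcripts were present in all 5 pMT-10 libraries and nearly absent in both BL/6 libraries. Xist had 11904 and 8140 counts in pMT-10 CMPs against 9308 and 8745 in BL/6 CMPs. The BL/6 CMP libraries thus held Xist with almost no Y-linked transcripts, while the pMT-10 CMP libraries held both. The sex make-up of the CMP libraries therefore differed between the strains and cannot be fully told apart from strain. Of the 2 LSK CD150+CD48+ libraries, replicate 1 held Xist (2431 counts) and Y-linked transcripts, and replicate 2 held Y-linked transcripts with almost no Xist (2 counts). A sex difference behind the whole pattern was predicted to return between them. The slope across 2961 called autosomal genes (replicate 2 minus replicate 1) was -0.055 ± 0.006 (bootstrap SE over genes). It cannot decide the question, since both libraries held Y-linked transcripts and the share of male cells in replicate 1 is unknown. There is also a single library on each side, so sex stays open for these genes. X-linked genes were called as often (27.8%) as genes not placed on X or Y (28%).

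The second pattern is the rise of interferon-γ and MHC class II genes in pMT-10 CMPs, which may be a response to IL-10 overexpression in this strain. That link is a hypothesis and was not tested. The IL-10 and STAT3 response list was not called between the CMPs (camera adjusted p = 0.881). The chip alone is argued against by a comparison within chip 2. There the interferon-γ list was higher in pMT-10 HSC than in BL/6 CMPs by a median of 3.391 (95% bootstrap interval over genes 1.899 to 4.834). That interval does not cover the spread between samples, with 1 HSC library, and cell type differs there as well. Mature B cells, macrophages or dendritic cells in the sort are also argued against: 4 class II genes summed to 574 and 974.5 CPM in pMT-10 CMPs against 2.22 and 4.93 in BL/6 CMPs, while 29 markers of those cells summed to 34.0 and 35.1 against 38.3 and 44.2 CPM, a log2 ratio of -0.249 ± 0.104 (SE). The 10 macrophage markers were at 0 CPM in both pMT-10 CMP libraries. A difference in substrain stays open. So does a difference in sex, since the slope above cannot decide it and was not run on these lists alone. The class II genes summed to 2169 CPM in LSK CD150+CD48+ replicate 2, which had almost no Xist, and to 3063 CPM in replicate 1. They were thus not higher in the library without Xist, although these are single libraries.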
